A study of Mus musculus with 6 samples.

How the data were processed

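Gene expression was measured on 6 one-colour Agilent arrays of mouse embryonic stem cells. The titles of the samples put 3 arrays in a wild-type group (WT) and 3 in a group in which Tet1, Tet2 and Tet3 were knocked out (TKO). Tet1, Tet2 and Tet3 encode the dioxygenases that oxidise 5-methylcytosine in DNA. Per the labels, the TKO cells were derived from the WT line, all samples were grown at the same time in 2i medium on mouse embryonic feeder cells, feeders were removed and the cells moved to matrigel before collection, and RNA of each sample came from a single dish. The replicates are therefore separate dishes of 1 WT line and of the TKO cells made from it. P-values measure only the spread between these dishes, which holds no spread between independently derived lines or clones. The labels do not say which exons were altered, so a probe outside the altered part checks nothing.

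The files were scanner output of Agilent Feature Extraction, version 11.5.1.1 per the submitters' processing notes. Per the file headers, the processed signal, the mean signal and the local background of each spot are intensity values on a linear scale, and the processed signal had been background-subtracted and detrended within each array but not normalized between arrays. The deposited flags of each spot (well above background, saturated, outlier) are values of 0 or 1, which count as another unit (other). The authors also deposited a table of processed values for 55821 probes, whose scale and centring the sources used here do not state. Set against the scanner values, each of its columns was the log2 of the processed signal shifted by a constant (Pearson r from 0.99999 to 1.0 across probes, with 99% of probes within 0.005 of the constant shift), and the 75th percentile of each deposited column was 0. Its column medians were -3.97, -3.97 and -4.03 for the WT arrays and -3.9, -3.74 and -3.82 for the TKO arrays. The values therefore appeared to be log2 signals centred on the 75th percentile, which the sources used here do not state.

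Each array held 62976 spots, of which 59305 were not controls, for 55681 probes. Between 51.9% and 58.5% of spots were well above background, and 0 spots were saturated. Negative controls differed between the rows of the slide. The 3 WT arrays and TKO replicate 1 lay in array row 1, and TKO replicates 2 and 3 lay in row 2, where they spread more widely (14.11 and 15.12 intensity units, against 7.23 to 8.95 in row 1). All arrays were on 1 slide and in 1 scan, so no slide or scan block could be fitted. The small number of arrays limits the precision of every value.

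Control spots and spots marked as outliers were left out, and spots of the same probe were averaged on the log2 scale. Each value was the log2 of the processed signal minus the 75th percentile of that array. A probe was kept if it was well above background on at least 3 of the 6 arrays, whichever group these belonged to, which left 30728 probes. Each gene name was represented by its kept probe with the highest mean over all 6 arrays, which gave 21558 tested genes, 14012 of them with a gene symbol that is not a clone, predicted or accession identifier. Gene names are those of the array design and can be old. Names of 21921 probes were accessions or transcript identifiers, of which 0 matched the gene table given, so those names were kept. Positions are on mouse build mm9 per the file headers, and 511 probes had none.

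TKO and WT arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with two-sided tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A total of 24 gene lists with 599 member names, of which 5 had no probe name to match and 9 were synonyms or paralogs that matched a gene already in the list (585 genes left), were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, and so were the genes of each of 21 chromosomes. The lists covered DNA methylation machinery, naive and general pluripotency, formative and primed epiblast, the 2-cell-like state, germline and meiosis, the Rhox cluster, imprinted genes, DNA damage response and repair, mitosis and chromosome segregation, DNA replication, p53 targets, telomere maintenance, primitive endoderm, mesoderm and primitive streak, neuroectoderm, trophoblast, fibroblast (feeder) markers, Wnt targets and regulators, the Nodal pathway, FGF/ERK targets, the interferon response, glycolysis, Hox genes and Y-chromosome genes. Groups, tests, lists, alternative settings and the rule for naming genes were chosen before the data were examined.

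Named genes were Tet1, Tet2 and Tet3 with every probe; the 12 largest rises and 12 largest falls among called genes with a gene symbol whose TKO values all lay on one side of the WT values; up to 3 higher and 3 lower called members of each list; and any member of the DNA methylation and pluripotency lists. Some genes that this rule names are not reported here. The alternative settings were normexp background correction (offset 50), quantile normalization, median centring, no filter, a filter requiring signal on all 6 arrays, the mean of a gene's probes, the authors' value table, a variance trend, replicate number as a block, leaving out each array, camera with an estimated correlation, the rotation test fry, which compares a set with no change and not with other genes, and a 1.5-fold limit. Camera with an estimated correlation also takes its degrees of freedom from the 6 arrays and not from the number of genes. Few sets can pass then, so a call lost in that setting decides little. Windows of 10 Mb with at least 20 tested genes, the array row as a block, the first array row alone, and list tests without the genes of chromosomes 1, 8, 10, 11 and Y were added after the data were seen.

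The pipeline was tested on simulated data made from the spread of these arrays, with 50 genes changed at each of several sizes. It recovered 66% of genes changed by 0.5 on the log2 scale, 76% of those changed by 1, 90% of those changed by 2 and 98% of those changed by 4, and 6.2% of its calls were false. The simulated spread was independent between genes, and far more genes were called in the real data (59.7%). These rates therefore do not carry over to the real comparison.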

Results

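The arrays measured RNA of mouse embryonic stem cells in 3 WT dishes and 3 TKO dishes, the latter lacking Tet1, Tet2 and Tet3 per the labels. The comparison asks how gene expression differs between cells with and without these 3 enzymes. The 75th percentile of the processed signal lay between 366.9 and 412.9 intensity units on the 6 arrays. Pearson correlations across tested genes, which are not independent replicates, were 0.997 to 0.9975 between WT arrays, 0.994 to 0.995 between TKO arrays and 0.9634 to 0.9669 between groups. The first principal component held 85.6% of the variance and separated the groups. Levels below are log2 signals relative to the 75th percentile of each array, and differences are TKO minus WT with n = 3 dishes per group.

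Tet1 and Tet2 RNA was lower in all 3 TKO dishes than in any WT dish, and still measurable. The brightest Tet1 probe (A_55_P2122997, chromosome 10, 62274448 to 62274507) read 3.84, 3.88 and 3.81 in the WT dishes and 2.42, 2.52 and 2.47 in the TKO dishes, a difference of -1.37 ± 0.045 (SE; adjusted p = 1.02e-05). The TKO level was 38.7% of the WT level. The brightest Tet2 probe (A_55_P2081303, chromosome 3, 133126751 to 133126810) read 3.88, 3.84 and 3.91 in WT and 0.85, 1.01 and 0.97 in TKO. Tet2 was thus 7.65-fold lower (log2 difference -2.94 ± 0.056 SE, adjusted p = 2.99e-06). The brightest Tet3 probe (A_55_P2175260, chromosome 6, 83319720 to 83319779) read -1.59, -1.80 and -1.86 in WT and -2.09, -1.85 and -2.03 in TKO. The difference of -0.24 ± 0.099 (SE) did not pass the test (adjusted p = 0.0904). Whether Tet3 was called depended on the processing: it passed with normexp (-0.195), quantile normalization (-0.349) and median centring (-0.439) and without TKO replicate 2 (-0.308), and in no other alternative, over a range of -0.439 to -0.157.

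Probes of the same gene differed. A second Tet2 probe fell by 3.23 ± 0.062 (SE) on the log2 scale, whereas probe A_55_P2074075 differed by -0.43 ± 0.196 (SE; adjusted p = 0.111). The other Tet1 probes fell by 1.37 and 1.16. Of the other Tet3 probes, A_51_P199339 was well above background on 0 arrays and A_52_P491273 on 1 WT array. Tet1 itself lies between 60 and 65 Mb of chromosome 10, where the median of 59 tested genes was 0.48 higher in TKO.

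**Figure D1:**
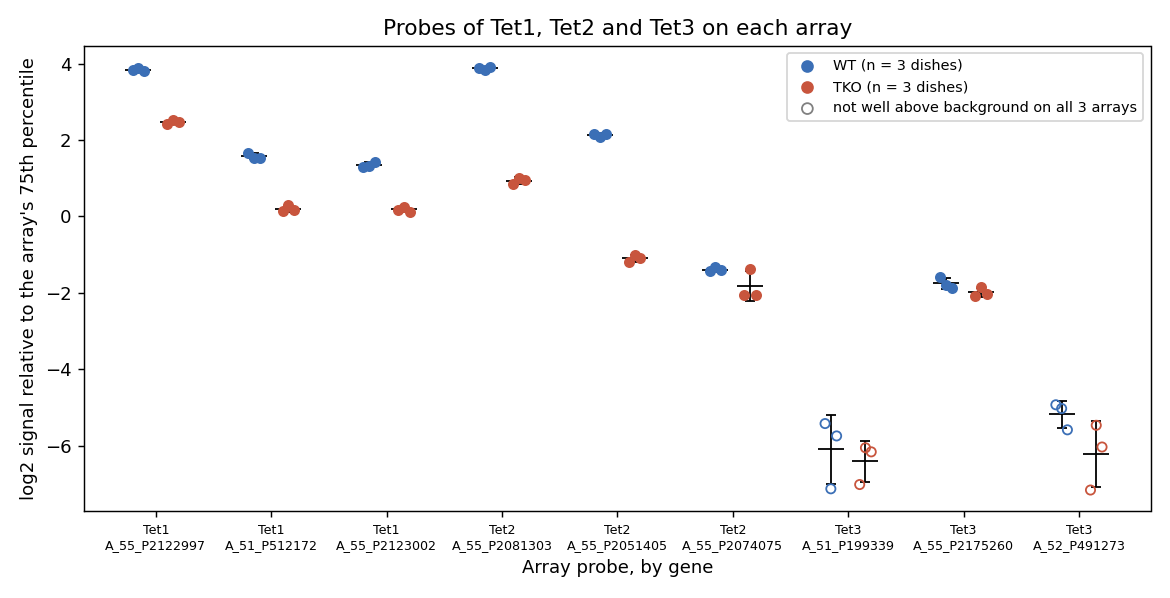
Log2 signal relative to the array's 75th percentile (vertical axis) for every probe of Tet1, Tet2 and Tet3 (horizontal axis), with a point per dish, the mean and the SD of 3 WT and 3 TKO dishes, and open points for probes not well above background on all 3 arrays of the group. All Tet1 probes and 2 of the 3 Tet2 probes lie lower in TKO, with the brightest Tet2 probe falling from a mean of 3.88 to 0.94.

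Large parts of the transcriptome differed between the cell populations. Some rises were in genes whose RNA was not well above background on any WT array, where a lower bound can be given and the genes cannot be ordered by size. Among them were Ubd, a ubiquitin-like protein, at least 254-fold higher (adjusted p = 8.45e-07), and Enpp2, the enzyme that makes lysophosphatidic acid, at least 123-fold higher (adjusted p = 4.03e-05). So were Trim12a (at least 88.5-fold, adjusted p = 2.72e-06), Pnp2 (at least 80.3-fold, adjusted p = 3.88e-06), the vitamin D-binding protein gene Gc (at least 73.2-fold, adjusted p = 7.46e-07) and the protease inhibitor gene Serpina3m (at least 70.6-fold, adjusted p = 4.36e-05). Large falls were in Xaf1, a binding partner of the apoptosis inhibitor XIAP, at -7.06 ± 0.135 (SE; adjusted p = 2.13e-06), and Kbtbd11 at -6.13 ± 0.234 (SE; adjusted p = 1.23e-05). Each bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the lowest signal well above background or the probe's own signal, whichever was higher.

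Other large rises were in Reg2 (at least 38.3-fold, adjusted p = 1.38e-06), Zfp874a (at least 30.9-fold, adjusted p = 2.05e-05) and Serpina3c (at least 24.97-fold, adjusted p = 9.18e-06). Also among them were the Wnt ligand gene Wnt8a (at least 22.6-fold, adjusted p = 2.7e-06) and Insm1, a zinc finger factor of neuroendocrine cells, at 6.13 ± 0.088 (SE), which 2 of the 3 WT arrays measured. Falls with signal on all arrays included Olfr224 (-5.20 ± 0.162 SE) and the homeobox gene Rhox13 (-4.74 ± 0.039 SE). No TKO array measured Dcstamp, which acts in fusion of osteoclasts (at least 20.9-fold lower, adjusted p = 8.42e-06), or the defensin gene Defa3 (at least 11.45-fold lower, adjusted p = 9.47e-05). The same held for Pla2g4e (at least 6.71-fold lower, adjusted p = 2.29e-05) and the muscle gene Myot (at least 6.18-fold lower, adjusted p = 3.34e-05). Syt10 (-5.15 ± 0.367 SE) and Raet1a (-4.37 ± 0.220 SE) were measured on 2 TKO arrays each, and Defa1 (-4.58 ± 0.116 SE) on 1.

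In all, 12860 of 21558 tested genes (59.7%) passed the threshold in limma, 6463 higher and 6397 lower in TKO. At least 2-fold changes passed for 2944 genes, 1598 higher and 1346 lower. These counts use the measured differences, also for genes not well above background in one group. The 3 TKO values of 14571 genes (67.6%) did not overlap the 3 WT values, against 10% by chance. The balance of directions depended on how arrays were scaled: centred on the median instead, the median gene difference moved from -0.008 to -0.209. Then 3826 called genes were higher and 9486 lower, with 1214 and 1929 at 2-fold. With normexp background correction, 1426 genes passed at 2-fold. With the array row as a block, differences rest on TKO replicate 1 against the WT arrays, because row 2 held only TKO arrays. They equal those of the first row alone, with a median gene difference of -0.012 in both. Both fits were chosen after the data were seen.

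Both de novo DNA methyltransferase genes were higher in TKO. Dnmt3b rose by 1.48 ± 0.061 (SE), or 2.79-fold (adjusted p = 1.57e-05), and Dnmt3a by 1.45 ± 0.037 (SE), or 2.73-fold (adjusted p = 4.05e-06). The largest rise in this list was in Dppa3, a maternal factor that protects methylation in the zygote, 52.8-fold (5.72 ± 0.081 SE, adjusted p = 1.22e-06). The maintenance methyltransferase gene Dnmt1 (-0.07 ± 0.044 SE, adjusted p = 0.203), its partner Uhrf1 (-0.08 ± 0.051 SE, adjusted p = 0.23) and the glycosylase gene Tdg (-0.09 ± 0.036 SE, adjusted p = 0.0688), which was positive with the mean of its probes, did not pass. Prdm14, which represses methyltransferase genes and lies in the lowered part of chromosome 1, fell by 0.76 ± 0.050 (SE), and Apobec1 by 0.76 ± 0.041 (SE). Of 20 tested members of the DNA methylation machinery, 10 were higher, 7 lower and 3 not past the threshold (10 and 8 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.649).

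Several genes of the naive pluripotent state fell and genes of the formative epiblast rose. Zfp42, a widely used naive marker, fell 16.8-fold (-4.07 ± 0.049 SE, adjusted p = 1.09e-06), and Tfcp2l1 (-1.65 ± 0.053 SE), Nr5a2 (-1.36 ± 0.048 SE), Tcl1 (-1.12 ± 0.078 SE), Klf4 (-1.06 ± 0.039 SE) and Tbx3 (-1.05 ± 0.053 SE) each fell more than 2-fold. Core factor genes moved less: Pou5f1 fell by 0.42 ± 0.103, Sox2 by 0.36 ± 0.040 and Nanog by 0.31 ± 0.049 (SE). Of 24 tested naive and general pluripotency genes, 7 were higher, 14 lower and 3 not past the threshold (7 and 14 adjusted over the list alone). The list was not called (median -0.34, adjusted p = 0.0652), and its adjusted p was 0.634 without the genes of chromosomes 1, 8, 10, 11 and Y, a test chosen after the data were seen. That test left out 5 genes of this list, among them Zfp42, Tfcp2l1 and Nr5a2 with the largest falls, so it does not show that chromosome shifts account for them. Zfp42 and Klf2 lie on the lowered chromosome 8 (median -0.22), and Tfcp2l1 and Prdm14 in the lowered part of chromosome 1 (median -0.28). Each of these genes fell by more than the median of its region. Nr5a2 lies on chromosome 1 outside the lowered part. Dppa2 (0.49 ± 0.090 SE), Fgf4 (0.46 ± 0.048 SE) and Nr0b1 (0.39 ± 0.040 SE) rose. Dppa3, also expressed in naive cells but counted in the DNA methylation list, went against these falls, with a rise of 5.72 ± 0.081 (SE).

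Of 11 tested formative and primed epiblast genes, 10 were higher and 1 lower, also when adjusted over the list alone. The signalling gene Fgf5, not well above background on any WT array, was at least 8.82-fold higher (adjusted p = 8.63e-05). Zic2 rose 8.13-fold (3.02 ± 0.085 SE, adjusted p = 5.01e-06) and Grhl2, a regulator of epithelial genes, rose 4.95-fold (2.31 ± 0.064 SE, adjusted p = 4.87e-06). In contrast, Otx2, an early factor of the formative state, fell 2.61-fold (-1.39 ± 0.106 SE, adjusted p = 0.000143). The list was called (median 1.48, adjusted p = 0.000365), and its adjusted p was 0.375 with an estimated correlation, the highest of 19 camera alternatives, which started at 9.92e-07.

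**Figure D2:**
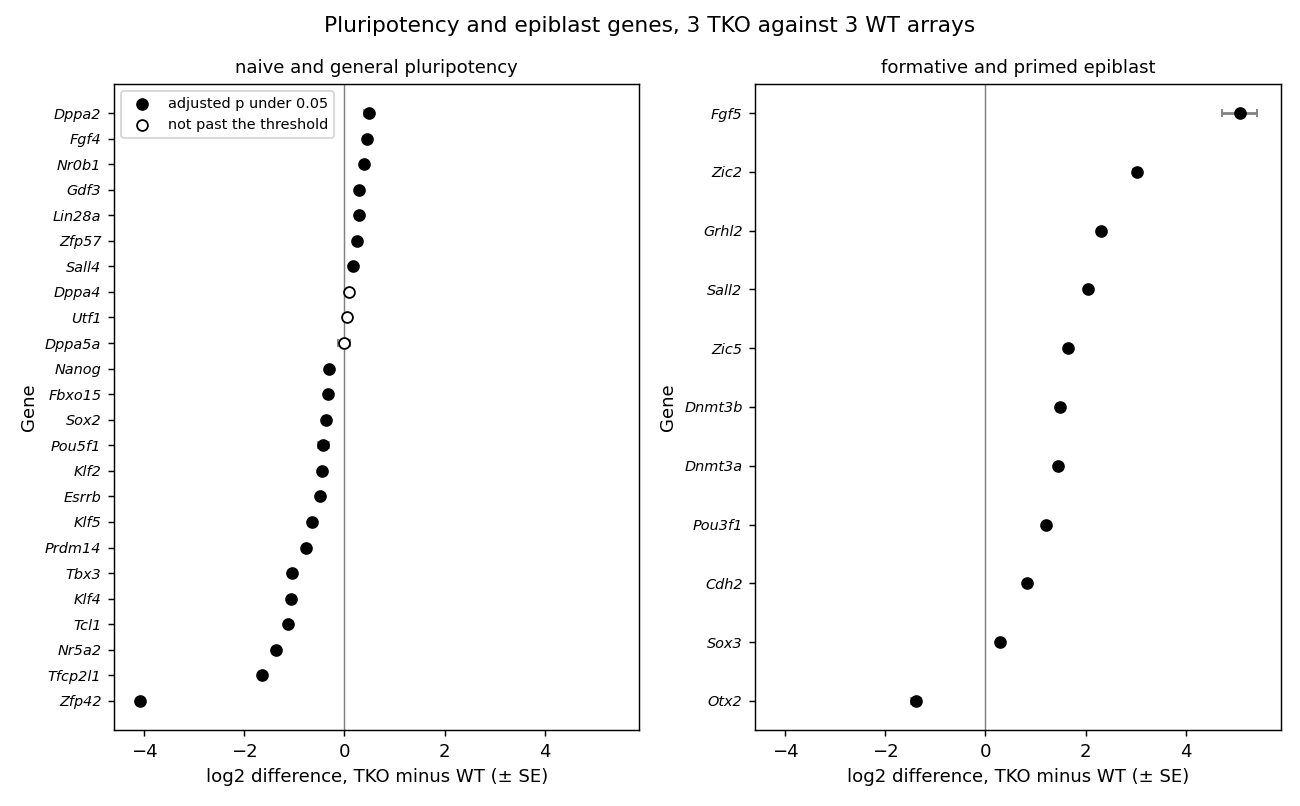
Log2 difference, TKO minus WT with its SE (horizontal axis), for all tested members of 2 fixed gene lists (vertical axis), from 3 dishes per group, with filled points for adjusted p under 0.05. Naive genes extend to -4.07 for Zfp42 and 10 of 11 formative genes lie above 0, while the plotted Fgf5 value rests on WT signals not well above background, Sall4, Dppa4 and Utf1 change sign with median centring, and Dppa5a with quantile normalization.

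Germline genes, many of which are silenced by promoter methylation in other cells, were mostly lower in TKO. Rpl10l, a testis ribosomal protein gene, fell 10.5-fold (-3.39 ± 0.046 SE, adjusted p = 1.21e-06), the meiotic cohesin gene Stag3 4.79-fold (-2.26 ± 0.061 SE, adjusted p = 4.53e-06) and the helicase gene D1Pas1 4.43-fold (-2.15 ± 0.042 SE, adjusted p = 2.31e-06). In the opposite direction, the synaptonemal complex gene Sycp1 rose by 1.64 ± 0.078, the germ cell helicase gene Ddx4 by 1.05 ± 0.056 and the meiosis entry gene Stra8 by 0.93 ± 0.074 (SE). Of 28 tested germline and meiosis genes, 6 were higher, 17 lower and 5 not past the threshold (6 and 18 adjusted over the list alone). This list was called (median -0.74, adjusted p = 0.0202), with an adjusted p of 0.497 with an estimated correlation, the highest of 19 camera alternatives, which started at 0.000519. Median centring (0.0528) and the stricter filter (0.0645) also ended the call.

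The X-linked Rhox homeobox cluster split. Rhox9 rose by 2.37 ± 0.086, Rhox6 by 1.95 ± 0.131 and Rhox4a by 1.03 ± 0.191 (SE), while Rhox13 fell by 4.74 ± 0.039, Rhox10 by 3.96 ± 0.342 and Rhox1 by 0.34 ± 0.091 (SE). That made 4 of 7 tested Rhox genes higher and 3 lower, also adjusted over the list alone, and no call (adjusted p = 0.706). The median (0.95) and camera pointed up, and the mean (-0.39) and fry, which tests against no change and not against other genes (adjusted p = 1.21e-05), pointed down.

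Imprinted genes, which are expressed from the copy of a single parent, changed in both directions. Mest and Peg3 rose 42.6-fold (5.41 ± 0.048 SE, adjusted p = 6.23e-07) and 17.8-fold (4.16 ± 0.163 SE, adjusted p = 1.34e-05), and Usp29, a neighbour of Peg3, was at least 10.7-fold higher (adjusted p = 5.07e-06). Mirg and Meg3, of the same cluster on chromosome 12, fell 15.6-fold (-3.97 ± 0.160 SE, adjusted p = 1.47e-05) and 8.85-fold (-3.15 ± 0.077 SE, adjusted p = 3.66e-06). The growth regulator gene Grb10 fell 2.48-fold, although it lies on the raised chromosome 11. Of 35 tested imprinted genes, 20 were higher, 10 lower and 5 not past the threshold (20 and 10 adjusted over the list alone), and the list was not called (adjusted p = 0.0581). Camera alternatives gave 0.0115 to 0.375.

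Genes of the 2-cell-like state, a rare state of stem cell cultures, were more often higher than lower. Tmem92, on chromosome 11, rose by 1.90 ± 0.134 and Gm13119 by 1.56 ± 0.069 (SE), Tcstv3 rose by 0.97 ± 0.132 (SE) with signal on 1 WT array, and Zfp352 fell by 0.31 ± 0.058 and AF067063 by 0.27 ± 0.065 (SE). Of 14 tested members, 7 were higher, 2 lower and 5 not past the threshold, also adjusted over the list alone, with no call for the list (adjusted p = 0.162).

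Mitosis and chromosome segregation genes were slightly lower in TKO. The condensin gene Ncapg fell by 0.85 ± 0.061, the cyclin gene Ccnb2 by 0.71 ± 0.032 and the cohesin gene Stag1 by 0.61 ± 0.054 (SE). The kinase gene Aurkc rose by 1.12 ± 0.062, Stag2 by 0.55 ± 0.042 and the securin gene Pttg1, on chromosome 11, by 0.39 ± 0.076 (SE). Of 46 tested members, 6 were higher, 24 lower and 16 not past the threshold, also adjusted over the list alone. The list was called (median -0.18, adjusted p = 0.0443), and its adjusted p was 0.497 with an estimated correlation, in a range over the camera alternatives from 0.00128 to 0.497. Leaving out WT replicate 3 (0.0589), TKO replicate 2 (0.0674) or TKO replicate 3 (0.0599) ended the call, as did quantile normalization (0.103), the stricter filter (0.0645), replicate number as a block (0.0551), the array row as a block (0.104) and the first array row alone (0.117).

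DNA replication genes went the same way without passing as a list. Prim2, a primase subunit gene, rose 9.04-fold (3.18 ± 0.045 SE, adjusted p = 1.22e-06) against the direction of its part of chromosome 1. Gins1 (0.56 ± 0.046 SE) and Cdc6 (0.53 ± 0.036 SE) also rose, while Gins4 (-1.03 ± 0.041 SE) and Gins2 (-0.91 ± 0.035 SE), both on chromosome 8, and the sliding clamp gene Pcna (-0.73 ± 0.051 SE) fell. Among 37 tested members, 7 were higher, 20 lower and 10 not past the threshold, also adjusted over the list alone (adjusted p = 0.0579).

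Genes of the DNA damage response moved both ways. The checkpoint kinase gene Atm rose by 1.31 ± 0.052 (SE), and Lig3 by 0.99 ± 0.039 and Brca1 by 0.84 ± 0.101 (SE), both on chromosome 11. The histone gene H2afx fell by 1.18 ± 0.037, the recombination gene Brca2 by 1.09 ± 0.042 and the glycosylase gene Neil3, on chromosome 8, by 0.97 ± 0.048 (SE). Of 56 tested genes, 18 were higher, 25 lower and 13 not past the threshold (18 and 26 adjusted over the list alone), with no call (adjusted p = 0.391). Among 28 tested p53 targets, 15 were higher, 6 lower and 7 not past the threshold, also adjusted over the list alone (adjusted p = 0.0652). Among them were rises of 1.93 ± 0.037 in Plk3, 1.39 ± 0.073 in Sesn1, which lies in the raised part of chromosome 10, and 1.099 ± 0.048 in Gadd45a, and falls in Aen (-0.70 ± 0.035), Phlda3 (-0.60 ± 0.069) and Perp (-0.37 ± 0.034; all SE). Among 19 tested telomere genes, 5 were higher, 9 lower and 5 not past the threshold, also adjusted over the list alone (adjusted p = 0.323). The telomere-binding factor gene Terf1, in the lowered part of chromosome 1, fell 3.11-fold (-1.64 ± 0.076 SE, adjusted p = 2.29e-05), and Tep1 and Obfc1 fell by 0.71 ± 0.051 and 0.56 ± 0.039 (SE). Ten1, Nhp2 and Wrap53, all on chromosome 11, rose by 0.77 ± 0.054, 0.63 ± 0.046 and 0.43 ± 0.044 (SE).

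Markers of differentiated lineages changed gene by gene. In the primitive endoderm list, the transcription factor gene Hnf4a fell 19.3-fold (-4.27 ± 0.090 SE, adjusted p = 2.62e-06) and the laminin gene Lama1 fell by 1.76 ± 0.057 (SE). The endocytic receptor gene Lrp2 rose 10.3-fold (3.36 ± 0.086 SE, adjusted p = 4.03e-06), and Lamb1 rose by 1.44 ± 0.039 (SE). Of 17 tested members, 7 were higher, 6 lower and 4 not past the threshold, also adjusted over the list alone (adjusted p = 0.764). Of 14 mesoderm and primitive streak genes, 5 were higher, 3 lower and 6 not past the threshold, also adjusted over the list alone (adjusted p = 0.722), with a median of -0.04 but a mean of 0.75 and a test pointing up. Besides Wnt8a, its rises included the chromosome 11 genes Hand1 (at least 4.66-fold, adjusted p = 0.00109) and Wnt3 (at least 3.15-fold, adjusted p = 0.00108), and Mesp2 (-0.85 ± 0.127), Eomes (-0.74 ± 0.043) and Gsc (-0.65 ± 0.146; all SE) fell. Of 15 neuroectoderm genes, 6 were higher, 6 lower and 3 not past the threshold (7 and 6 adjusted over the list alone; adjusted p = 0.817). Olig2 rose by 4.35 ± 0.207 (SE) with signal on 1 WT array and Sox11 by 2.57 ± 0.052 (SE). Conversely, Lhx2 (-1.61 ± 0.15), Ncam1 (-1.43 ± 0.046) and Sox1, on chromosome 8 (-1.11 ± 0.072; all SE), fell.

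Trophoblast markers were more often higher than lower. The trophectoderm factor gene Cdx2 was at least 3.01-fold higher (adjusted p = 0.00128), Gata3 rose 7.91-fold (2.98 ± 0.098 SE, adjusted p = 7.8e-06) and Plet1 rose 6.01-fold (2.59 ± 0.044 SE, adjusted p = 1.6e-06). Falls included Tfap2a (-1.92 ± 0.091), Gcm1 (-1.43 ± 0.083), whose probe the files place on chromosome 7 and which was positive with the mean of its probes, and Gata2 (-1.06 ± 0.086; all SE). Of 16 tested members, 10 were higher, 4 lower and 2 not past the threshold, also adjusted over the list alone, and the list was not called (adjusted p = 0.0581). Hox genes, which pattern the body axis, were lower. Hoxc11 was at least 1.87-fold lower (adjusted p = 0.000241), Hoxc13 fell by 2.10 ± 0.566 and Hoxc4 by 1.91 ± 0.084 (SE). The chromosome 11 genes Hoxb2, Hoxb4 and Hoxb13 rose by 0.68 ± 0.133, 0.59 ± 0.073 and 0.55 ± 0.070 (SE). Of 23 tested Hox genes, 3 were higher, 12 lower and 8 not past the threshold (3 and 13 adjusted over the list alone), and the list was called (median -0.48, adjusted p = 0.0443). With an estimated correlation its adjusted p was 0.375, in a range over the camera alternatives from 0.000894 to 0.375. Leaving out WT replicate 3 (0.0562), the stricter filter (0.305), the array row as a block (0.0787) and median centring (0.0528) each ended this call.

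Fibroblast markers, fixed because the stem cells had been kept on feeder cells, were higher in TKO. The smooth muscle actin gene Acta2 rose by 1.20 ± 0.059, the collagen cross-linking enzyme gene Lox by 0.99 ± 0.051 and Tagln by 0.97 ± 0.039 (SE). Conversely, the receptor gene Pdgfrb fell by 2.26 ± 0.151, Vim by 0.50 ± 0.036 and Fn1, in the lowered part of chromosome 1, by 0.23 ± 0.046 (SE). Of 23 tested members, 15 were higher, 3 lower and 5 not past the threshold (16 and 3 adjusted over the list alone). The list was called (median 0.35, adjusted p = 0.0443), with an adjusted p of 0.431 with an estimated correlation, in a range over the camera alternatives from 0.0231 to 0.431. Leaving out WT replicate 1 (0.0526), WT replicate 3 (0.0562) or TKO replicate 1 (0.054) ended the call, as did quantile normalization (0.0536), the stricter filter (0.0645) and leaving out the genes of chromosomes 1, 8, 10, 11 and Y (0.0654).

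Signalling genes changed without any of their lists being called. Targets of FGF/ERK signalling were mostly lower, with 2 of 17 higher, 9 lower and 6 not past the threshold, also adjusted over the list alone (adjusted p = 0.106). The feedback inhibitor genes Spry4, measured on 2 TKO arrays, and Spry2 fell by 2.85 ± 0.185 and 2.07 ± 0.088 (SE), and Etv1 fell 4.46-fold (-2.16 ± 0.078 SE, adjusted p = 1.05e-05). In this list, Fosl1 (0.96 ± 0.133 SE) and Spred2, on chromosome 11 (0.55 ± 0.043 SE), rose. Of 12 Nodal pathway genes, 8 were higher and 4 lower, also adjusted over the list alone (adjusted p = 0.162). The Nodal antagonist gene Lefty1 rose 8.33-fold (3.06 ± 0.079 SE, adjusted p = 4.17e-06) and Lefty2 4.02-fold (2.01 ± 0.058 SE). The activin subunit gene Inhbb, in the lowered part of chromosome 1, fell 15.3-fold (-3.94 ± 0.044 SE, adjusted p = 9.52e-07). The Nodal co-receptor gene Tdgf1 fell by 1.05 ± 0.042 (SE) with its brightest probe and was positive with the mean of its probes, and the inhibitor gene Smad7 fell by 0.96 ± 0.032 (SE).

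Among 14 Wnt targets and regulators, 10 were higher and 4 lower, also adjusted over the list alone (adjusted p = 0.0841). Lef1 rose by 2.06 ± 0.105 (SE), Znrf3 and Rnf43, both on chromosome 11, rose by 1.16 ± 0.109 and 1.13 ± 0.146 (SE), and the secreted antagonist genes Sfrp4 and Sfrp5 changed by -1.40 ± 0.045 and -1.04 ± 0.082 (SE). Without the genes of chromosomes 1, 8, 10, 11 and Y, this list gave an adjusted p of 0.756, in a range over the camera alternatives from 0.0311 to 0.756. Of 12 tested interferon response genes, 5 were higher, 4 lower and 3 not past the threshold (6 and 4 adjusted over the list alone; adjusted p = 0.479). Oasl2 was at least 10.8-fold higher (adjusted p = 0.000542), Cxcl10 rose by 2.75 ± 0.132 and Bst2, against the direction of chromosome 8, by 1.53 ± 0.040 (SE). In the other direction, Ifit2 was at least 1.13-fold lower (adjusted p = 0.00153) and Oasl1 fell by 0.50 ± 0.062 (SE). Glycolysis genes were mostly lower, with 2 of 20 higher, 12 lower and 6 not past the threshold, also adjusted over the list alone (adjusted p = 0.0581). Pfkp fell by 1.28 ± 0.131, the hexokinase gene Hk2 by 0.86 ± 0.068 and Pdk1 by 0.61 ± 0.063 (SE), and Pfkm and Pkm rose by 0.72 ± 0.036 and 0.38 ± 0.033 (SE).

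Whole chromosomes and parts of them shifted. On chromosome 11, 73.8% of 1616 tested genes were higher in TKO, with a median of 0.34 (adjusted p = 2.62e-09, and 0.0638 with an estimated correlation), and the median was 0.34, 0.35 and 0.32 in the 3 TKO dishes taken singly. Chromosome 8 was lower (1173 genes, median -0.22, adjusted p = 0.00033, and 0.235 with an estimated correlation), as was chromosome 1 (1232 genes, median -0.12, adjusted p = 0.0233, and 0.436 with an estimated correlation). On chromosome 1 the shift lay between 0 and 130 Mb (705 genes, median -0.28), against 0.02 for the 527 genes beyond. A part of chromosome 10 between 30 and 60 Mb was higher (141 genes, median 0.67, 78% of genes higher), with -0.07 for the 770 genes outside the raised parts of that chromosome. Other autosomes had a median of -0.015. The boundaries of these parts were chosen after the windows were seen, of which 33 of 255 passed the threshold. Of these, 29 lay on chromosomes 1, 8, 10 and 11 and 4 elsewhere: chromosome 5 at 90 to 100 Mb (median 0.31, adjusted p = 0.00783) and chromosome 18 at 10 to 20 Mb (0.38, 0.0276) were higher, and chromosome 9 at 80 to 90 Mb (-0.23, 0.00831) and chromosome 14 at 0 to 10 Mb (-0.41, 0.013) were lower.

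Chromosome Y genes were called higher as a set (10 tested genes, median 0.61, adjusted p = 0.0336, and 0.44 with an estimated correlation). Singly, 6 of them passed as higher and 0 as lower. Of the fixed Y-chromosome genes, 4 of 4 tested were higher, also adjusted over the list alone, too few for a list test. The translation factor gene Eif2s3y rose 5.33-fold (2.41 ± 0.040 SE, adjusted p = 1.54e-06) and Zfy1 was at least 7.61-fold higher (adjusted p = 8.4e-05). Uty was at least 4.08-fold higher (adjusted p = 0.000699) and Ddx3y rose 1.81-fold (0.85 ± 0.057 SE). For chromosomes 11, 8, 1 and Y the setting with an estimated correlation thus gave no call. It gave the highest adjusted p of 18 camera alternatives, which started at 5.66e-10, 0.000125, 0.0101 and 0.0122. For chromosome 11 the estimate was 0.01, the same as the preset value, so its size does not account for the change there. That setting takes its degrees of freedom from the few arrays, so its lack of calls does not decide on these shifts. Chromosome Y was also not called without WT replicate 2 (0.0526) or TKO replicate 2 (0.0584), with either other filter (0.159 and 0.205) with the array row as a block (0.0903) or in the first row alone (0.0877), nor chromosome 1 with median centring (0.0527) or no filter (0.159).

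**Figure D3:**
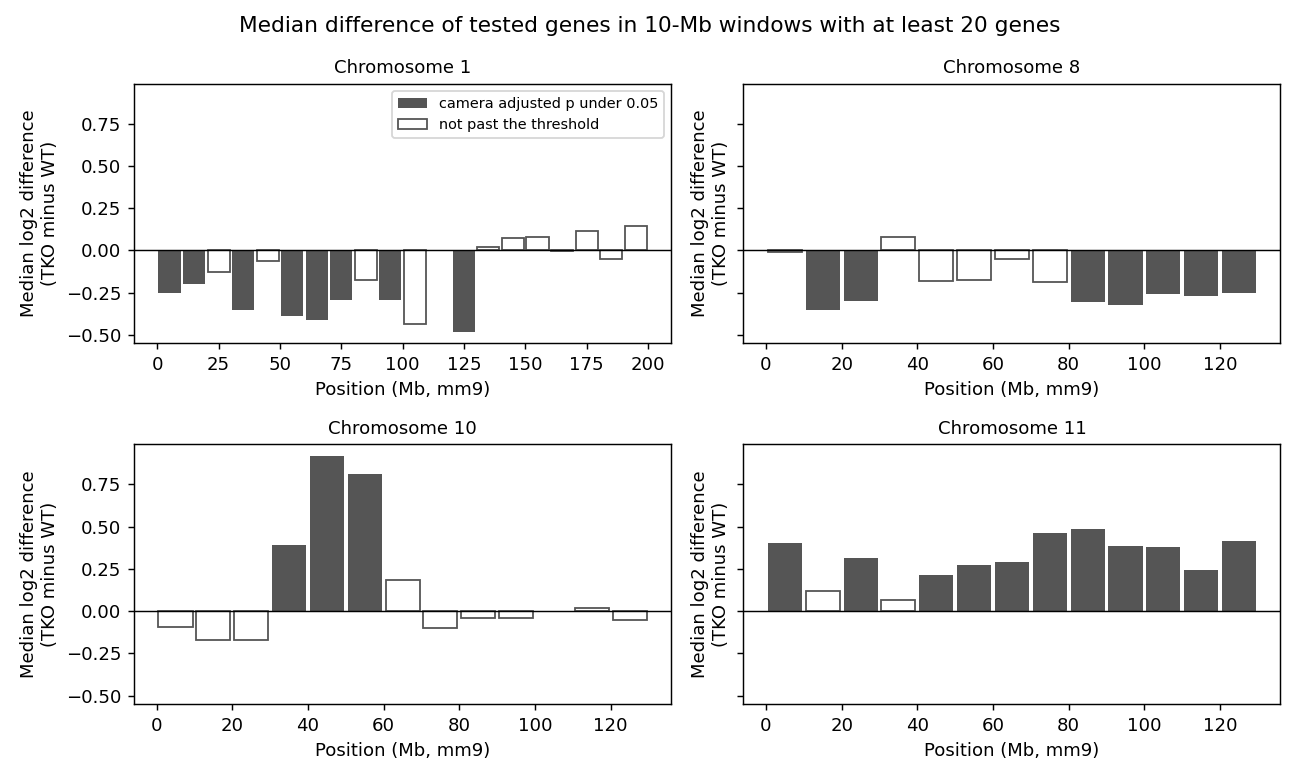
Median log2 difference, TKO minus WT, of the tested genes in each 10-Mb window with at least 20 genes (vertical axis) along chromosomes 1, 8, 10 and 11 (horizontal axis, Mb on mm9), from 3 dishes per group, with filled bars for camera adjusted p under 0.05. All 13 windows of chromosome 11 lie above 0, from 0.07 to 0.49, and the highest window, at 40 to 50 Mb of chromosome 10, reaches 0.92, while windows of other chromosomes, 4 of which passed, are not drawn.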

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

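The array row as a block, the first array row alone and the list tests without chromosomes 1, 8, 10, 11 and Y were tests chosen after the data were seen. Because row 2 held only TKO arrays, the row block and the first row alone give the same differences, of TKO replicate 1 from the WT arrays. They are therefore not separate checks. Slide as a block was not run, because all arrays were on 1 slide. Across the alternatives 10088 to 13429 genes passed the threshold, and Tet1 (-1.57 to -1.30) and Tet2 (-3.14 to -2.20) stayed lower and past it. Of 3164 alternative values of 188 named genes, 3083 had the same direction and side of the threshold, 65 lost their call, 6 gained one and 10 changed sign. Signal over background limits dim genes, since 438 of the genes counted as changed at least 2-fold have only a bound in one group. Some of these bounds lie under 2-fold, such as 1.13 for Ifit2 and 1.87 for Hoxc11. Except where the setting itself tests fewer genes or arrays or takes fewer degrees of freedom, the cause of each change below was not tested. Values for lists and chromosomes are adjusted p.

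With normexp, 1426 genes passed at 2-fold (746 higher, 680 lower), Tet3 passed at -0.195 and DNA replication at 0.0461. With quantile normalization Tet3 passed at -0.349, Dppa5a turned to 0.043, and mitosis and chromosome segregation (0.103) and fibroblast (feeder) markers (0.0536) lost their calls. With median centring, 3826 genes were called higher, Tet3 passed at -0.439, and Dppa4 (-0.105), Sall4 (-0.023) and Utf1 (-0.157) turned negative. That setting called imprinted genes (0.0115), trophoblast (0.0104) and Wnt targets and regulators (0.0311), and not germline and meiosis (0.0528), Hox genes (0.0528) or chromosome 1 (0.0527). At 1.5-fold, 5756 genes passed.

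Without a filter, naive and general pluripotency (0.00427), DNA replication (0.00321), trophoblast (0.0475), Wnt targets and regulators (0.039), FGF/ERK targets (0.0283) and glycolysis (0.00389) were called. Chromosomes 1 and Y (0.159 each) were not, and primitive endoderm (0.868) and chromosomes 3, 6 and 16 (0.999 each) changed direction, uncalled. With the stricter filter, germline and meiosis, mitosis and chromosome segregation, fibroblast (feeder) markers (0.0645 each), Hox genes (0.305) and chromosome Y (0.205) lost their calls, and mesoderm and primitive streak (0.438), neuroectoderm (0.828) and chromosome 19 (0.908) changed direction, uncalled. With the mean of a gene's probes, Gcm1 (0.201), Tdgf1 (0.101) and Tdg (0.052) turned positive, imprinted genes (0.0321), DNA replication (0.017), trophoblast (0.017) and glycolysis (0.0247) were called, and neuroectoderm (0.781) and chromosome 3 (0.968) changed direction. The authors' value table called imprinted genes (0.0438), DNA replication (0.0437) and trophoblast (0.0437).

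Replicate numbers did not pair the dishes: deviations from the group mean correlated at -0.069, -0.024 and 0.006 between arrays of the same number, and 1 TKO array was closest to the WT array of its own number. With replicate number as a block 11617 genes passed, and mitosis and chromosome segregation (0.0551) did not. With the array row as a block, 10566 genes passed, mitosis and chromosome segregation (0.104), Hox genes (0.0787) and chromosome Y (0.0903) lost their calls and chromosome 5 (0.998) changed direction. The first row alone, where TKO has 1 array assumed to vary like the WT arrays, gave 10088 genes and lost mitosis and chromosome segregation (0.117) and chromosome Y (0.0877), with chromosome 5 (0.964) reversed. Without chromosomes 1, 8, 10, 11 and Y, fibroblast (feeder) markers (0.0654) lost their call and mesoderm and primitive streak (0.78) changed direction.

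Leaving out each array in turn gave -0.308 to -0.157 for Tet3, past the threshold without TKO replicate 2, and -0.085 to 0.083 for Dppa5a. Ranges were 0.0256 to 0.0562 for fibroblast (feeder) markers (lost without WT replicate 1 at 0.0526, WT replicate 3 at 0.0562 and TKO replicate 1 at 0.054), 0.0345 to 0.0674 for mitosis and chromosome segregation (lost without WT replicate 3 at 0.0589, TKO replicate 2 at 0.0674 and TKO replicate 3 at 0.0599) and 0.0256 to 0.0562 for Hox genes (lost without WT replicate 3). DNA replication and trophoblast ranged from 0.0422, without WT replicate 2, to 0.0674, glycolysis from 0.0318, without TKO replicate 1, to 0.0814, and chromosome Y from 0.0133 to 0.0584 (lost without WT replicate 2 at 0.0526 and TKO replicate 2 at 0.0584). Chromosome 5 ranged from 0.943 to 0.995, with its direction changed without TKO replicate 2 (0.971).

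With an estimated correlation 0 lists and 0 chromosomes were called: formative and primed epiblast gave 0.375, germline and meiosis 0.497, mitosis and chromosome segregation 0.497, fibroblast (feeder) markers 0.431, Hox genes 0.375, and chromosomes 1, 8, 11 and Y 0.436, 0.235, 0.0638 and 0.44. The estimate was 0.01 for chromosome 11, equal to the preset value, and -0.032 for Hox genes, below it. The size of the correlation therefore does not account for the loss of either call. This setting also takes its degrees of freedom from the few arrays, under which few sets could pass. These losses therefore do not decide on the calls. The test fry, which does not compare a set with other genes, called DNA methylation machinery (2.28e-07), naive and general pluripotency (2.31e-05), the 2-cell-like state (1.31e-06), imprinted genes (1.31e-06), DNA damage response and repair (0.000303), DNA replication (0.00257), p53 targets (0.000122), telomere maintenance (0.00471), primitive endoderm (0.0499), mesoderm and primitive streak (1.8e-05), neuroectoderm (0.0119), trophoblast (1.52e-06), Wnt targets and regulators (0.000303), the Nodal pathway (0.0367), FGF/ERK targets (1.8e-05), the interferon response (0.000561) and glycolysis (0.0157), and the Rhox cluster in the other direction (1.21e-05). For chromosomes it gave 0.0052 (2), 0.252 (3), 0.0015 (4), 0.726 (6), 0.00153 (7), 0.00155 (9), 0.0052 (10), 0.383 (14), 0.208 (16), 0.955 (18), 0.126 (19) and 0.00909 (X), with 3, 6, 14, 16, 18 and 19 changed in direction and uncalled.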

Other observations

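Tests of the array row, of strongly changed genes, of copy number and of feeder cells, and the search over gene families, were chosen after the results were seen, whereas the tests of second probes and of other splits of the arrays were set before their outcomes were known.

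The X-linked lymphocyte regulated (Xlr) genes, a family of neighbours on the X chromosome, fell together. All 7 tested members were lower in TKO, from -1.42 ± 0.160 (SE) in Xlr3a to -3.41 ± 0.052 (SE) in Xlr5b, with Xlr5a at least 3.48-fold lower, and the median was -2.64. Of 365 families formed from shared name stems with at least 6 tested members, this was the only one past the threshold (camera adjusted p = 0.00231). With an estimated correlation its adjusted p was 0.999, as it was for the next families, Ndufa and Gramd. That setting takes its degrees of freedom from the few arrays and could hardly pass any of 365 families, so it decides nothing here. All tested Xlr members were also lower and past the threshold in each other setting run on the genes, with medians from -2.84 with median centring to -1.78 with normexp. Whether probes of these related genes read one another's RNA was not tested, so the 7 values are not taken as independent.

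The shifts of chromosomes 11, 8 and 1 and of a part of chromosome 10 were weighed against 3 explanations. The tables argue against the array row as the source: TKO replicate 1, in the row of the WT arrays, alone gave a chromosome 11 median of 0.341, and 0.69, -0.22 and -0.29 for the raised part of chromosome 10, chromosome 8 and the lowered part of chromosome 1. A few strongly changed genes were not the source on chromosome 11, where 73.8% of the genes were higher in TKO against 48.5% on the other autosomes. A copy-number difference between the 2 cell populations may underlie the chromosome 11 shift. The 10th percentile of its genes lay 0.302 above that of the other autosomes (0.508 between 30 and 60 Mb of chromosome 10). This test replaced a look at windows whose outcome was already known. With 73.8% of the genes already seen to be higher, a raised 10th percentile was likely beforehand, so the test does not decide on copy number. The upper tail is the one to read in the lowered regions. The 90th percentile differed by -0.151 on chromosome 8 and -0.316 on the first 130 Mb of chromosome 1. It differed by -0.242 on chromosome 10 outside its raised parts, where the median differed by only -0.052. The upper tail thus does not set chromosome 8 apart from that part of chromosome 10. The 10th percentile does (-0.388 against -0.091), but a low tail moves with the falls already seen. RNA does not measure copy number, and regulation across these regions stays open.

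The changes of at least 2-fold were weighed against the behaviour of single probes. Of 1081 second probes of 718 such genes, 79.3% passed the threshold in the same direction and 4.3% in the opposite one, and their differences correlated with those of the first probes at 0.818 across probes, which are not independent replicates. This argues against probe sequence as the general cause, and says nothing of genes with 1 kept probe. The loss of the Tet enzymes, named by the design, and changes gained during derivation of the TKO cells remain untested, because both separate the same dishes.

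The higher fibroblast markers may reflect more feeder cells in the TKO dishes, which the values neither exclude nor require. The median of 8 tested matrix genes was 0.369 (range -0.153 to 0.659), which leaves feeder cells open. The abundant fibroblast genes Vim (-0.50) and Fn1 (-0.23) were lower in TKO, and Pdgfrb fell by 2.26. Fn1 lies in the lowered part of chromosome 1, whose median was -0.28, so its fall says little of feeder cells. By contrast, of the 6 members dimmest in WT, Col6a2 (WT level -3.11) rose by 0.49, Prrx1 (-2.47) by 0.47, Twist2 (-2.45) by 0.43 and Postn (-2.52) by 0.35. Twist1 (0.38, adjusted p = 0.298) and Dcn (-0.15, adjusted p = 0.642) did not pass. Feeders had been removed before collection per the labels, and a change of these genes in the stem cells themselves stays open.

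The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split alone reached its own result, 1 of 10, for each of 4 results. It gave 12860 genes past the threshold against at most 0 in any other split, 2944 at 2-fold against 0, 5 gene lists against at most 3, and 4 chromosomes against at most 2. Every other split puts TKO and WT arrays together in both groups, so the difference between TKO and WT widens the spread within them. Low gene counts there were fixed in advance, so the comparison does not decide on chance.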
